A study of Mus musculus with 9 samples.

How the data were processed

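Mouse embryonic stem cells of 3 established lines, E14, v6.5 and Oct4 GiP, were kept on gelatin in 3 culture conditions for 2 weeks, per the labels' protocols. The conditions were Serum, 2i and Paused, and Paused cells were those treated with INK128, an inhibitor of the mTor kinase, at 200 nM for 2 weeks. Each line gave 1 library per condition, 9 libraries in all and 3 per condition. Libraries were made from 250 ng of total RNA after mRNA purification, with ERCC spike-in RNA added to every sample and a directional kit, per the labels' protocols.

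The authors deposited 1 table with 18 value columns, 2 per library, and every column was matched to a library by its name (0 columns without a sample). The first column of each library holds FPKM, as the authors' run of Cuffnorm gave it, per the submitters' processing notes, which name mm10 as the genome build and give no version. The second column, headed as normalized expression, is the same FPKM multiplied by 1 constant per library. How Cuffnorm scaled the libraries to each other is not given; summed FPKM over all rows ran from 1451983 to 2133969. The constant was read from the values; how the authors made it, and whether from the spike-in, is not given in the sources used here. The aligner, the gene annotation and whether fragments were counted by strand are not given in the sources used here either. Without stated strand-aware counting, a gene and an antisense or overlapping neighbour are uncertain. Genes with near-identical copies, such as ribosomal protein genes and their pseudogenes, keratins 8 and 18, and the Zscan4 and Hspa1 genes, are uncertain too.

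The table has 29801 rows. Of these, 5644 (18.9%) carry no gene name and hold 52.8% to 64.0% of a library's summed FPKM; they were left out of the comparisons and tested apart. After 113 identical repeats were left out, 24044 named rows remained, of which 352 join several symbols, and 293 symbols stand on more than 1 row. In the table used here 0 rows are named as spike-in RNA, and whether rows without a gene name hold any is unknown. The table holds no read counts, so the depth of each library is unknown and no counting interval is given. A value of exactly 0 may be a failed estimate, since Eef1a1, a translation factor of every cell, is listed at 0 in all 9 libraries. Values of such genes are given per library.

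Genes with FPKM of 1 or more in at least 3 of the 9 libraries were tested, 12711 in all, among them 252 joined symbols and 209 small RNA genes. Limma-trend (limma 3.58.1, R 4.3.3) was fitted to log2(FPKM + 1) with all 9 libraries in 1 fit and the cell line as a block, and p-values were adjusted by Benjamini-Hochberg over the tested genes, with 0.05 as the threshold. A log2 fold change is on the log2(FPKM + 1) scale, which understates the change of low genes, and is given ± its limma standard error. Levels are given as the mean ± SD of the 3 libraries of a condition (n = 3). The lines are different cells grown in each condition. With the line as a block, p-values rest on the spread left after line and condition means are removed, pooled over the 3 conditions. They measure how much condition differences vary between these 3 lines, and not the differences between the lines themselves. The same fit was run relative to the median gene, by subtracting each library's median, and an F test was run over the 3 conditions. The pairing comes from the labelled cell line. Deviations from the condition means correlated across genes at -0.001 to 0.401 between libraries of the same line and at -0.243 to 0.094 between different lines. Single values were compared by exact permutation tests of 3 against 3 libraries, two-sided, which cannot give a p below 0.1.

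A set of 41 lists of pathways, complexes and cell type markers was fixed before the data were examined, as were the tests, the rule for naming genes and the alternatives other than those named below as added. Lists with at least 5 tested members, 40 of the 41, were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, beside camera with an estimated correlation and fry. A statement on a list rests on its count of called members. Counts adjusted over the list alone stand beside it. The genes named are, per comparison and direction, the 10 with the largest change among those called, with the same sign in all 3 lines and a mean FPKM of at least 5 in the higher condition. Predicted, small RNA and joined symbols are left out of these. To them come up to 4 members per list with the largest change among those called, or 2 where none is called, and a fixed panel of pluripotency, differentiation and growth genes. A gene named outside this rule is said to be so, and not every gene within it is reported here.

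The limma-trend fit and camera were tested on simulated data. For Paused against Serum with 12711 genes, 50 genes were changed at each of 4 sizes. The share called in the right direction was 10% at a log2 fold change of 0.5, 74% at 1 and 100% at 2 and 3, and 9 unchanged genes were called. Far fewer genes were changed than were called in the real libraries, which makes the adjusted threshold stricter in the simulation. These shares need therefore not hold for the real comparisons. A simulated shift of the lysosome list was found, with 0 other lists called. The simulated genes varied independently of each other, so this does not show how often camera calls lists falsely in the real libraries. The alternatives tried were pseudocounts of 0.1 and 5, other filters, no line block, other variance settings, a minimum fold, quantile normalisation, centring, the 6 libraries of a comparison alone, and leaving out each library and each line. The authors' normalized columns and the omission of small RNA genes and joined symbols were added after the table was seen. For the shared response, 100 pairs of unchanged groups were simulated against the same Serum libraries. Coordinates are from GENCODE release M21 on GRCm38, the assembly also called mm10, counted from 1. Figures were drawn with matplotlib 3.10.9.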

Results

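RNA was sequenced from mouse embryonic stem (ES) cells of 3 lines, E14, v6.5 and Oct4 GiP, the last a reporter line for the pluripotency gene Oct4. Each line was cultured in Serum, in 2i and in Paused conditions, which gave 9 libraries, 3 per condition and 1 per line in each. The name 2i usually stands for inhibitors of the kinases MEK and GSK3, and the labels give no composition. Paused cells received the mTor inhibitor INK128 at 200 nM for 2 weeks. The study asked how ES cells in a paused pluripotent state differ from those in Serum and 2i. Values are FPKM, and the depth of each library in reads is unknown. Between 11709 and 12112 named genes reached FPKM of 1 or more in a library, and Pearson correlations between libraries ran from 0.877 to 0.964 across genes, which are not independent replicates.

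The authors' per-library constants and the overall level of the libraries were compared before single genes. All samples carried spike-in RNA, and whether the constants come from it is not given in the sources used here. The constant by which the authors multiplied FPKM averaged 3.59 ± 0.17 in Serum, 2.80 ± 0.36 in 2i and 1.88 ± 0.095 in Paused (SD, n = 3). Paused stood at 0.485, 0.541 and 0.547 of Serum in E14, v6.5 and Oct4 GiP, a mean of 0.524 ± 0.034, and 2i at 0.776 ± 0.066 of Serum. Each of the 3 pairs of conditions was fully separated, with an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. In FPKM the median gene of a library differed by 0.025 (log2, SD 0.031 over the lines) between Paused and Serum, within the spread between lines (exact p = 0.4). In the same units 2i stood 0.11 (SD 0.011) above Serum and Paused 0.08 (SD 0.040) below 2i, each with exact p = 0.1. With the authors' constants the difference turned to -0.87 for Paused against Serum and to -0.24 for 2i against Serum, and became -0.63 for Paused against 2i. In FPKM the mean and the 75th percentile of genes put Paused below Serum, at -0.025 and -0.037. The scaling between libraries within Cuffnorm is not given in the sources used here and can fix the median gene, so these levels in FPKM do not measure amounts of RNA. On the authors' scale the median log2 fold change of all genes was -0.88, -0.33 and -0.56 in the 3 comparisons. All changes below are in FPKM, that is, relative to that shift.

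**Figure D1:**
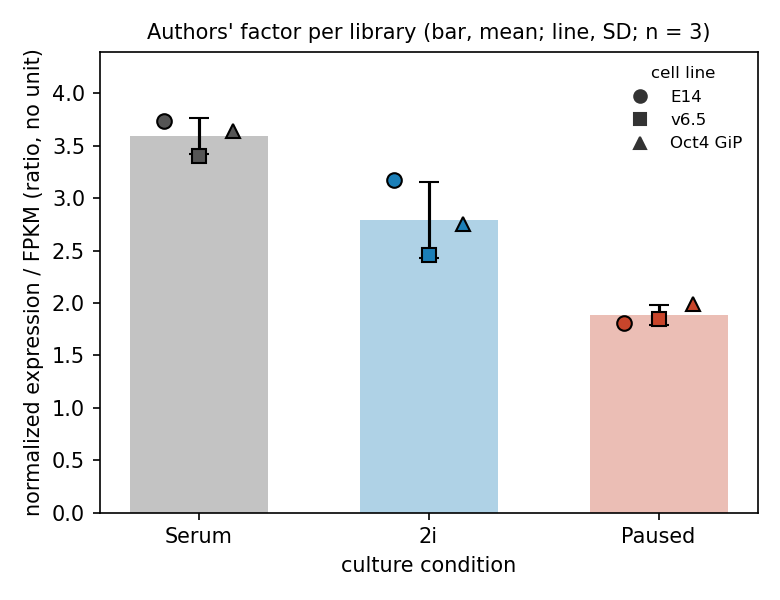
Ratio of the authors' normalized expression to FPKM in each library (y axis, no unit) for the 3 conditions (x axis), with bars at the mean and lines for the SD (n = 3). Paused libraries lie between 1.81 and 1.99, below all 2i libraries (2.45 to 3.17) and all Serum libraries (3.40 to 3.74).

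The libraries separated by condition and then by line. The first principal component, with 43.3% of the variance, set the 3 libraries of 2i (scores 58.0 to 58.5) apart from the other libraries (-36.7 to -16.8). The second, with 15.1%, set Paused (20.8 to 37.4) apart from Serum (-36.7 to -26.2). The third, with 11.4%, held v6.5 at 23.4 to 31.5 in every condition, against -27.5 to -2.93 for the other lines. The F test of limma-trend called 6970 of 12711 genes among the 3 conditions.

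**Figure D2:**
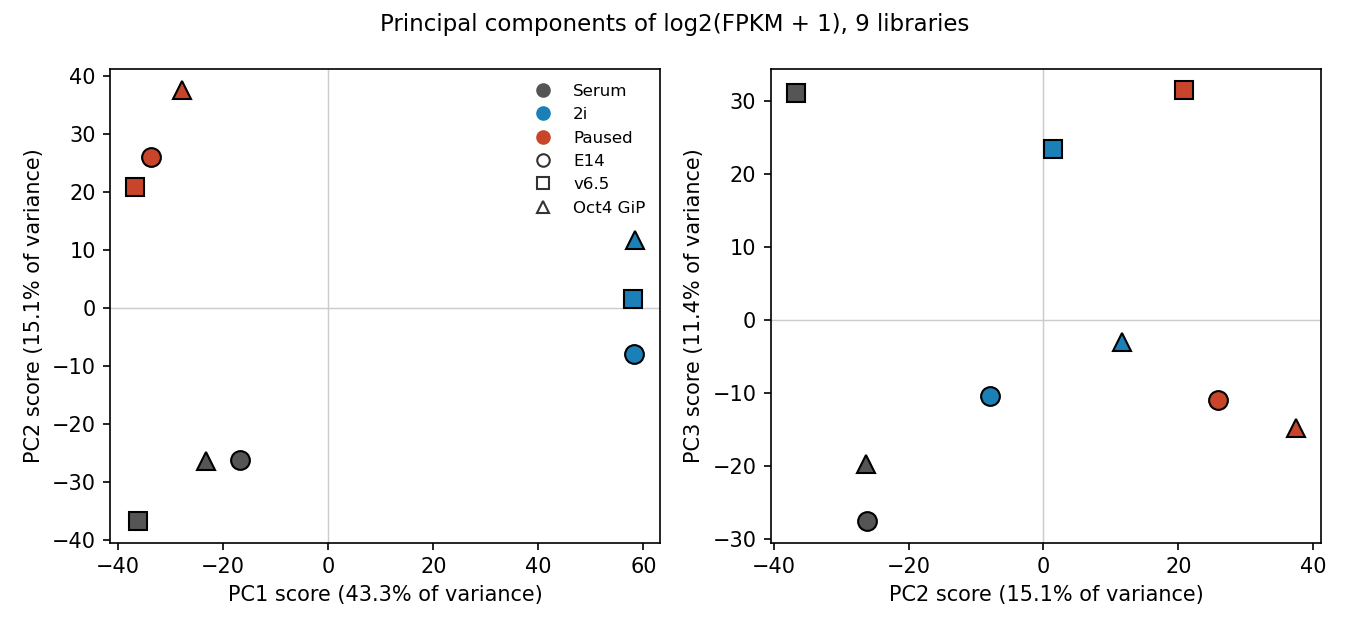
Scores of the 9 libraries on principal components 1 and 2 (left) and 2 and 3 (right) of log2(FPKM + 1), with the share of variance in brackets, color for the condition and shape for the cell line. The 2i libraries lie together at about 58 on the first component, and the second parts Paused from Serum.

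Paused cells were compared with Serum cells to find what changed under mTor inhibition. Irak1, a kinase of the interleukin-1 and Toll-like receptor pathways on chromosome X (74013914 to 74023918), rose from 17.1 ± 1.04 to 109 ± 2.94 FPKM (log2 fold change 2.60 ± 0.14, adjusted p = 0.0021). Klhl24, a target of FoxO factors that encodes an adaptor for ubiquitin ligases, rose from 9.08 ± 1.96 to 41.4 ± 4.29 FPKM (2.08 ± 0.11, adjusted p = 0.0021). Crebrf, a regulator of the stress factor CREB3, rose from 2.13 ± 0.124 to 11.5 ± 1.06 FPKM (2.00 ± 0.10), and Ephx2, the soluble epoxide hydrolase, rose by 2.23 ± 0.20. The calpain protease Capn3 rose from 2.07 ± 1.29 to 20.4 ± 11.5 FPKM (2.73 ± 0.26) and the octamer-binding Pou2f2 by 1.78 ± 0.20. Keratins of simple epithelia fell: Krt8 from 82.8 ± 70.7 to 6.73 ± 3.09 FPKM (-3.14 ± 0.64, adjusted p = 0.025), Krt19 (-2.92 ± 0.64) and Krt18 (-2.31 ± 0.52), the last not called without the line block. Tagln, an actin-binding protein of smooth muscle and mesenchymal cells, fell from 64 ± 46.2 to 5.73 ± 3.05 FPKM (-3.08 ± 0.48). So did the calcium-binding S100a6 (-2.71 ± 0.46), calponin Cnn1 (-2.15 ± 0.20), the keratinocyte 14-3-3 protein Sfn (-2.28 ± 0.40) and the autophagy receptor Calcoco2 (-2.99 ± 0.49). The X-linked homeobox gene Rhox5 (-2.63 ± 0.33) and the calmodulin-like Calml4 (-2.18 ± 0.34) fell too, and neither was called without the line block. The E14 Serum library held the highest levels, 161 FPKM of Krt8 against 24.4 in v6.5 and 62.6 in Oct4 GiP, and 114 FPKM of Tagln against 22.5 and 55.8. In all, 2311 of 12711 genes were called, 971 higher and 1340 lower, and 101 rose and 178 fell by a log2 fold change of 1 or more. The authors' scale gave 48 higher and 9779 lower. The count fell to 714, 775 and 12 without the Serum libraries of E14, v6.5 and Oct4 GiP, to 36, 36 and 10 without those of Paused, and to 1529 without the Oct4 GiP 2i library. Without all libraries of E14, v6.5 or Oct4 GiP it was 1, 5 and 2. Irak1, Klhl24 and Crebrf were the 3 of the 138 called named genes that stayed called without any single library (highest adjusted p 0.040, 0.043 and 0.040), and each of the others was lost without at least 1 library.

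Transcripts of mitochondrial energy production were lower in Paused than in Serum. Of 74 tested nuclear genes of oxidative phosphorylation, 44 fell and 0 rose (51 and 0 adjusted over the list alone), with a median of -0.39 ± 0.014 over the 3 lines. Atp5g1, a subunit of the ATP synthase ring, fell from 289 ± 30.1 to 149 ± 10.3 FPKM (-0.95 ± 0.07, adjusted p = 0.0062). Uqcrq of complex III fell (-0.91 ± 0.09), and Ndufa2 of complex I (-0.81 ± 0.08). Of 48 genes of the mitochondrial ribosome, 29 fell and 0 rose (37 and 0 adjusted over the list alone), with a median of -0.48 ± 0.019. Mrpl34 fell (-0.88 ± 0.07) and Mrps12 (-0.85 ± 0.11). In every line 67 of the 74 and 43 of the 48 genes were lower, against 4123 of all 12711. With a correction for transcript length and GC content the joint median of these 122 genes went from -0.42 ± 0.016 to -0.27 ± 0.035, and the number called lower from 74 to 32. Glycolytic genes fell in 7 of 20 cases and rose in 1 (7 and 1 adjusted over the list alone). Among those lower were lactate dehydrogenase Ldha from 773 ± 250.2 to 265 ± 39.2 FPKM (-1.51 ± 0.21), the glucose transporter Slc2a1 (-1.30 ± 0.18) and Tpi1 (-0.96 ± 0.15). Pdk1, the kinase that holds pyruvate dehydrogenase inactive, rose by 0.86 ± 0.18 in FPKM (-0.06 on the authors' scale). In the authors' columns 74, 48 and 17 genes of the 3 lists fell and 0 rose. Camera with its preset correlation called these 3 lists lower (adjusted p = 1.1e-14, 1.6e-12 and 0.0066), and none with an estimated correlation, where the adjusted p = 0.31, 0.31 and 0.48. The preset correlation called 21 of 40 lists in this comparison, another split of the same 6 libraries 17, fry 13, and the estimated correlation 0 (2 at an unadjusted p under 0.05). That other split put both libraries of a line in 1 group, and other splits with 1 library of each line per group gave at most 11.

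Genes of protein synthesis and of other anabolic pathways went down in part. Among 42 translation factors, 11 fell and 3 rose (13 and 4 adjusted over the list alone). Eef1d, an exchange factor of elongation, fell from 291 ± 26.3 to 159.7 ± 13.3 FPKM (-0.86 ± 0.16), and Eif6, which keeps ribosomal subunits apart, fell from 198 ± 7.58 to 126 ± 1.32 FPKM (-0.65 ± 0.06). Eif4ebp1, the translation repressor that mTor phosphorylates, fell from 745 ± 91.9 to 470.0 ± 49.9 FPKM (-0.66 ± 0.10). Of 41 genes of ribosome biogenesis 9 fell and 0 rose (11 and 0 adjusted over the list alone), Nop16 (-0.79 ± 0.09) and Nhp2 (-0.64 ± 0.07). Of 79 cytosolic ribosomal proteins 3 rose and 1 fell, 0 and 0 adjusted over the list alone, while in the authors' columns 79 were lower. Nucleotide synthesis had 6 of 20 genes lower and 0 higher (8 and 0 adjusted over the list alone), with Umps of the pyrimidine pathway at -0.60 ± 0.08. Cholesterol synthesis and uptake had 6 of 23 lower and 0 higher (6 and 0 adjusted over the list alone), with Idi1 at -1.04 ± 0.20, and the list's median was -0.72 in E14, -0.74 in v6.5 and 0.06 in Oct4 GiP. The amino acid response, genes induced by ATF4, had 8 of 31 lower and 0 higher (10 and 0 adjusted over the list alone). Psph and Psat1, enzymes of serine synthesis, fell (-1.21 ± 0.18 and -1.13 ± 0.20), and Psat1 was not called without the line block. Fads2 and Scd1, fatty acid desaturases, fell from 27.1 ± 5.88 to 8.01 ± 0.416 FPKM (-1.62 ± 0.14) and (-1.76 ± 0.30). Of 13 genes of fatty acid synthesis 3 fell and 0 rose (5 and 0 adjusted over the list alone). In the authors' columns 0 genes rose in these 7 lists, in the order given, and 41, 41, 79, 20, 23, 29 and 13 fell. For the same lists the adjusted p = 0.61, 0.64, 0.71, 0.48, 0.64, 0.61 and 0.61 with an estimated correlation.

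Lysosomal, autophagy and FoxO genes were in part higher in Paused in FPKM and lower on the authors' scale. On that scale 9779 of all 12711 genes were lower, so a fall there is shared by most genes. The medians of the 3 lists there, -0.69, -0.67 and -0.495, lay above the -0.88 of all genes. Of 40 lysosomal genes 13 rose and 0 fell in FPKM (15 and 1 adjusted over the list alone), with a median of 0.23 ± 0.007 over the lines, whereas in the authors' columns 0 rose and 25 fell. The cathepsins Ctsl and Ctsf rose from 48.6 ± 10.3 to 99.7 ± 10.4 FPKM (1.04 ± 0.15) and by 1.23 ± 0.21, and the hexosaminidase subunit Hexa by 0.87 ± 0.14. Of 32 autophagy genes 8 rose and 1 fell (9 and 2 adjusted over the list alone), against 0 and 22 in the authors' columns. Fnip1, a partner of folliculin at the lysosome, rose from 3.87 ± 0.23 to 8.67 ± 0.33 FPKM (0.99 ± 0.09), and Map1lc3a, an LC3 gene of the autophagosome, fell (-0.65 ± 0.09). Of 19 FoxO targets and genes of insulin receptor signalling 6 rose and 0 fell (7 and 0 adjusted over the list alone), against 1 and 10 in the authors' columns. Txnip, an inhibitor of glucose uptake, rose from 76.5 ± 12.5 to 169 ± 23.8 FPKM (1.14 ± 0.26). Ccng2, a cyclin of resting cells, rose by 0.85 ± 0.15, and the insulin receptor Insr by 0.77 ± 0.10, the last not called without the line block. With an estimated correlation the 3 lists had adjusted p = 0.59, 0.48 and 0.48. Among 35 components of the mTor pathway 3 rose and 6 fell in FPKM (5 and 9 adjusted over the list alone), against 0 and 25 in the authors' columns, and in FPKM their median was 0.06 while their mean was -0.04. The mTor inhibitor Deptor rose by 1.07 ± 0.18 and Rictor of complex 2 by 0.69 ± 0.10, while Ddit4, a stress-induced inhibitor of complex 1, fell from 33 ± 9.42 to 7.41 ± 3.28 FPKM (-2.07 ± 0.30). Mtor itself rose from 16.7 ± 2 to 25.8 ± 0.703 FPKM (0.60 ± 0.09) and the cyclin kinase inhibitor Cdkn1b from 17.9 ± 1.69 to 29 ± 4.1 FPKM (0.67 ± 0.08), and on the authors' scale Mtor, Cdkn1b, Rictor and Hexa had values below 0 (-0.30, -0.23, -0.14 and -0.03).

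Few pluripotency factors were called between Paused and Serum. Pou5f1 (Oct4) stood at 1596 ± 229 FPKM in Paused and 1435 ± 187 in Serum, Nanog at 144 ± 65.1 and 156 ± 102, and Esrrb, a receptor of naive cells, at 177 ± 70.3 and 108 ± 72.2. None of the 3 was called (adjusted p = 0.39, 0.91 and 0.23). Changes of about 0.5 may be missed. In the simulated data 10% of changes of that size were called. That share need not hold here, since far fewer genes were changed in the simulation than were called in the real libraries. The v6.5 Serum library held less Nanog, Esrrb and Klf4 (42.8, 25.2 and 12.2 FPKM) than those of E14 (239, 156 and 81.6) and Oct4 GiP (185, 144 and 63.2). Of 12 core factors 2 rose and 0 fell in FPKM (4 and 0 adjusted over the list alone), against 0 and 10 in the authors' columns. Called or not, 11 of these 12 and 15 of 16 naive factors had a log2 fold change above 0 in FPKM. The naive median was 0.012, 1.135 and 0.541 in E14, v6.5 and Oct4 GiP. On the authors' scale the core and naive medians were -0.677 and -0.365. Of 16 naive factors Stat3 rose by 0.33 ± 0.07 in FPKM (-0.59 on the authors' scale), not called without the line block, and Dppa3, a maternal factor of naive cells, fell from 28 ± 0.695 to 7.4 ± 5.24 FPKM (-2.07 ± 0.44). A list of p53 targets with some cyclin kinase inhibitors, which does not hold Cdkn1b, fell in 9 of 19 cases and rose in 0 (11 and 0 adjusted over the list alone), Perp, a desmosome gene, from 33.5 ± 5.2 to 9.74 ± 0.892 FPKM (-1.68 ± 0.29) and Phlda3 (-1.38 ± 0.14). Of 10 trophoblast markers, Krt8 and Krt18 among them, 5 fell and 0 rose (6 and 0 adjusted over the list alone). Of 7 markers of fibroblast feeder cells, Tagln among them, 5 fell and 0 rose (5 and 0 adjusted over the list alone). In the authors' columns 2 naive, 19 p53, 8 trophoblast and 7 feeder genes fell and 0 rose. With an estimated correlation the core, naive, p53, trophoblast and feeder lists had adjusted p = 0.48, 0.64, 0.58, 0.58 and 0.48. Genes of mitosis rose in 6 of 25 cases in FPKM and fell in 0 (6 and 1 adjusted over the list alone), against 0 and 22 in the authors' columns, with Top2a, which untangles chromosomes, at 0.60 ± 0.08. Their median was -0.01, -0.03 and 0.04 in the 3 lines. Of 29 genes of the G1/S transition 6 fell and 1 rose (11 and 2 adjusted over the list alone), against 27 and 0 in the authors' columns, with Tk1 and Rrm2, which make nucleotides for replication, at -0.86 ± 0.18 and -0.78 ± 0.15 and cyclin Ccne2 at 0.80 ± 0.11. On the authors' scale Top2a and Ccne2 had values below 0 (-0.33 and -0.04). For these 2 lists the adjusted p = 0.71 and 0.64 with an estimated correlation.

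Culture in 2i was compared with Serum as the reference for naive pluripotency. Cdx1, a homeobox factor and Wnt target on chromosome 18 (61018862 to 61036199), rose from 2.46 ± 1.94 to 86.8 ± 28.3 FPKM (log2 fold change 4.78 ± 0.43, adjusted p = 0.0013). Bhmt and Dmgdh, neighbouring genes of betaine metabolism on chromosome 13, rose by 3.83 ± 0.26 and 3.62 ± 0.36, and the water and glycerol channel Aqp3 rose from 12.6 ± 6.33 to 183 ± 33.2 FPKM (3.88 ± 0.48). Nupr1, a stress-induced chromatin protein, rose from 13.5 ± 5.01 to 154 ± 79.8 FPKM (3.37 ± 0.19). The germ cell genes Dazl and Stra8 rose by 3.22 ± 0.31 and 4.73 ± 0.87, and Stra8 stood at 257 FPKM in E14 against 29.5 and 43.3 in v6.5 and Oct4 GiP. Spink1, a trypsin inhibitor on chromosome 18 (43728082 to 43737557), fell from 46.1 ± 16.8 to 0.269 ± 0.282 FPKM (-5.17 ± 0.34, adjusted p = 0.00072). Tagln fell (-4.75 ± 0.48), the membrane-bound transcription factor Myrf (-4.29 ± 0.24), the myosin light chain Myl9 (-4.17 ± 0.20) and the BMP target Id2 (-4.14 ± 0.28). The cysteine-rich Plac8 (-4.27 ± 0.28), the lactate exporter Slc16a3 (-4.13 ± 0.33) and the imprinted growth regulator Phlda2 (-4.13 ± 0.41) were lower as well, and the homeobox gene Crxos (3.71 ± 0.30) and the immune receptor Cd84 (3.58 ± 0.36) higher. In all, 5161 genes were called, 2762 higher and 2399 lower, against 2181 and 3263 relative to the median gene and 1240 and 4538 on the authors' scale. The count was 2960 without the Oct4 GiP Serum library, 3204 without the Oct4 GiP 2i library, 2532 without v6.5, 1216 without Oct4 GiP and 2985 in the 6 libraries alone. Of 170 called named genes, 127 stayed called without any single library.

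Signalling targets and factors of later pluripotency were lower in 2i. Of 16 targets of ERK, the kinase downstream of MEK, 12 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -1.14 ± 0.147 over the lines. Egr1, an immediate early transcription factor, fell from 23.5 ± 5.65 to 0.259 ± 0.0974 FPKM (-4.26 ± 0.42). Spry4, a feedback inhibitor of the pathway, fell from 43.3 ± 10.1 to 2.64 ± 1.11 FPKM (-3.62 ± 0.23), and the ERK phosphatases Dusp4 and Dusp6 (-3.53 ± 0.34 and -2.39 ± 0.23). Of 14 formative and primed factors 11 fell and 0 rose (12 and 0 adjusted over the list alone), with Pou3f1 (Oct6) at -3.92 ± 0.47 and Tcf15 at -2.99 ± 0.31. The DNA methyltransferase cofactor Dnmt3l fell from 361 ± 131 to 28.4 ± 19 FPKM (-3.86 ± 0.29) and Dnmt3b (-2.70 ± 0.35). Of 12 core factors 8 fell and 0 rose (10 and 0 adjusted over the list alone), with the RNA-binding Lin28a from 212 ± 44 to 18.1 ± 12.9 FPKM (-3.66 ± 0.35) and Utf1 at -2.25 ± 0.11. Of 18 Myc factors and targets 10 fell and 0 rose (11 and 0 adjusted over the list alone), with Myc from 61 ± 5.07 to 5.57 ± 1.86 FPKM (-3.27 ± 0.15) and Mycn at -2.03 ± 0.19. Of 16 naive factors 6 rose and Dppa3 fell (6 and 1 adjusted over the list alone), with Tfcp2l1 at 2.58 ± 0.56, Tbx3 at 2.55 ± 0.62 and Prdm14 at 2.15 ± 0.51. Nanog rose from 156 ± 102 to 361 ± 28.3 FPKM (1.53 ± 0.46, adjusted p = 0.038) and Klf4 by 1.86 ± 0.52. The change was largest in v6.5, where the Serum library was low: Nanog differed by 0.46, 3.09 and 1.04 in E14, v6.5 and Oct4 GiP, Klf4 by 0.79, 3.66 and 1.12, and the median of the naive list by 0.20, 2.01 and 0.44 (SD 0.985). In the authors' columns the ERK, formative, core and Myc lists had 16, 13, 12 and 15 genes lower and 0 higher, and the naive list 4 higher and 1 lower. With an estimated correlation the ERK, formative, core, Myc and naive lists had adjusted p = 0.18, 0.37, 0.22, 0.23 and 0.64. Nanog was also not called without the line block. Without the Oct4 GiP Serum library, among others, Nanog, Klf4, Tbx3 and Prdm14 were not called, and their highest adjusted p without 1 library was 0.098, 0.085, 0.070 and 0.065.

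Genes of lipid metabolism, of the amino acid response and of the lysosome rose in 2i, and genes of ribosome production fell. Cholesterol synthesis and uptake had 19 of 23 genes higher and 0 lower (20 and 0 adjusted over the list alone). The synthase Hmgcs1 stood at 120 FPKM in 2i and 52.6 in Serum, and Msmo1 of the later steps rose from 21.8 ± 8.1 to 76.2 ± 23.5 FPKM (1.76 ± 0.23). The amino acid response had 18 of 31 higher and 0 lower (21 and 1 adjusted over the list alone), with asparagine synthetase Asns from 115 ± 50 to 508 ± 142 FPKM (2.17 ± 0.18) and the arginine transporter Slc7a1 at 1.75 ± 0.17. The lysosome list had 29 of 40 higher and 1 lower (29 and 1 adjusted over the list alone), with Hexa at 1.81 ± 0.14 and Lamp2, a lysosomal membrane protein, at 1.80 ± 0.11. Fatty acid synthesis had 9 of 13 and fatty acid oxidation 12 of 18 higher, and 0 lower in either (10 and 12 higher adjusted over the list alone). Scd1 rose from 10.5 ± 3.08 to 63 ± 8.35 FPKM (2.50 ± 0.30) and Cpt1a, the gate of mitochondrial fatty acid import, from 6.08 ± 2.27 to 48.1 ± 12.4 FPKM (2.81 ± 0.16). Of 41 genes of ribosome biogenesis 37 fell and 0 rose (39 and 0 adjusted over the list alone), with Nolc1 from 218 ± 9.85 to 116 ± 5.15 FPKM (-0.91 ± 0.07). Of 42 translation factors 23 fell and 2 rose (25 and 3 adjusted over the list alone), with Eif5a at -0.91 ± 0.10. Of 79 cytosolic ribosomal proteins 15 fell and 0 rose, 0 adjusted over the list alone, and the direction of the list turned under quantile normalisation (adjusted p = 0.27). The share that fell was like that of all genes, 2399 of 12711, so these genes did not stand out as lower. Glycolysis had 10 of 20 lower and 3 higher (12 and 5 adjusted over the list alone), with Ldha at -2.15 ± 0.21 and hexokinase Hk1 at 2.10 ± 0.27. Oxidative phosphorylation had 19 of 74 higher and 2 lower in FPKM (14 and 1 adjusted over the list alone), against 1 and 15 in the authors' columns. The share higher in FPKM was little above that of all genes, 2762 of 12711. In those columns cholesterol had 9 higher and 0 lower, the amino acid response 12 and 3, the lysosome 16 and 3, fatty acid synthesis 8 and 0 and fatty acid oxidation 6 and 3. Ribosome biogenesis had 41, translation factors 37 and cytosolic ribosomal proteins 69 lower and 0 higher there, and glycolysis 12 lower and 2 higher. With an estimated correlation these 10 lists had adjusted p = 0.43, 0.39, 0.37, 0.38, 0.22, 0.37, 0.38, 0.64, 0.37 and 0.64. Camera with its preset correlation called 20 of 40 lists, another split of the 6 libraries also 20, fry 26, and the estimated correlation 0 (4 at an unadjusted p under 0.05). That other split put both libraries of a line in 1 group, and other splits with 1 library of each line per group gave at most 16.

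Paused and 2i were compared to set the paused state against the naive one. Lefty1, an inhibitor of Nodal signalling on chromosome 1 (180935022 to 180938400), was higher in Paused, from 2.09 ± 2.79 to 140.4 ± 58.1 FPKM (log2 fold change 5.79 ± 0.74, adjusted p = 0.0021), as were Spink1 (5.76 ± 0.34), Myrf (5.43 ± 0.24), the growth factor Fgf17 (4.27 ± 0.21) and the ectonucleotidase Enpp3 (4.25 ± 0.35). Lower in Paused were Ly6a, the stem cell antigen Sca-1, from 63.8 ± 49.4 to 0.208 ± 0.0217 FPKM (-5.33 ± 0.58), Aqp3 (-5.26 ± 0.48), Cdx1 (-5.03 ± 0.43), Nupr1 (-4.78 ± 0.19), Rhox5 (-4.28 ± 0.33), Crxos (-4.21 ± 0.30) and the meiotic recombination gene Rec114 (-4.03 ± 0.35). The ERK targets had 13 of 16 genes higher and 0 lower (13 and 0 adjusted over the list alone), with Spry4 from 2.64 ± 1.11 to 72.6 ± 16 FPKM (4.36 ± 0.23). All 12 core pluripotency factors were higher (12 adjusted over the list alone), with Lin28a at 3.85 ± 0.35. Formative factors had 10 of 14 higher and 0 lower (10 and 0 adjusted over the list alone), with Dnmt3l, a cofactor outside that list, at 4.25 ± 0.29. On the authors' scale these 3 lists had 11, 4 and 8 genes higher and 0 lower, and in FPKM their adjusted p = 0.17, 0.17 and 0.54 with an estimated correlation. Myc rose from 5.57 ± 1.86 to 83.2 ± 16.3 FPKM (3.70 ± 0.15), and Nanog fell from 361 ± 28.3 to 144 ± 65.1 FPKM (-1.44 ± 0.46, adjusted p = 0.043), not called without the E14 Paused library (adjusted p = 0.13) or without the line block. In all, 5638 genes were called, 2517 higher and 3121 lower in Paused, against 3180 and 2645 relative to the median gene and 789 and 6922 on the authors' scale. The count was 3526 without the E14 Paused library, and 3726, 3569 and 2041 without E14, v6.5 and Oct4 GiP. Of 168 called named genes, 123 stayed called without any single library.

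Genes of lipid metabolism, of the amino acid response and of oxidative phosphorylation were lower in Paused than in 2i. All 23 tested genes of cholesterol synthesis and uptake fell (23 adjusted over the list alone), with Hmgcs1 from 120.0 ± 18.3 to 30 ± 5.3 FPKM (-1.97 ± 0.21) and Msmo1 at -2.46 ± 0.23. The amino acid response had 23 of 31 lower and 2 higher (24 and 2 adjusted over the list alone), with Asns from 508 ± 142 to 82.3 ± 18.2 FPKM (-2.59 ± 0.18) and the kinase-like stress gene Trib3 at -2.57 ± 0.16. Oxidative phosphorylation had 55 of 74 lower and 0 higher (60 and 0 adjusted over the list alone), with Atp5g1 at -1.16 ± 0.07. Fatty acid synthesis had 10 of 13 and fatty acid oxidation 12 of 18 lower and 0 higher (12 and 12 lower adjusted over the list alone), with Scd1 from 63 ± 8.35 to 2.41 ± 1.08 FPKM (-4.27 ± 0.30) and Cpt1a at -1.75 ± 0.16. Lysosomal genes fell in 18 of 40 cases and rose in 2 (20 and 2 adjusted over the list alone), with cathepsin Ctsb at -1.62 ± 0.08. In the authors' columns these 6 lists had 23, 28, 71, 13, 17 and 35 genes lower, with 1 lysosomal gene higher and 0 in the others. Ddit4 fell from 93.2 ± 33.4 to 7.41 ± 3.28 FPKM (-3.52 ± 0.30), and Cdkn1a (p21), a brake on the cell cycle, from 113 ± 18.3 to 13.4 ± 2.27 FPKM (-2.98 ± 0.17). Ribosome biogenesis had 25 of 41 higher and 0 lower in FPKM (31 and 0 adjusted over the list alone), against 0 and 8 in the authors' columns. Cytosolic ribosomal proteins had 32 of 79 higher and 1 lower (36 and 1 adjusted over the list alone), against 0 and 39 in those columns. Heatr1, needed for ribosomal RNA synthesis, was higher by 0.86 ± 0.11. With an estimated correlation the cholesterol, amino acid, oxidative phosphorylation, fatty acid synthesis and oxidation, lysosome, ribosome biogenesis and ribosomal protein lists had adjusted p = 0.55, 0.54, 0.26, 0.54, 0.17, 0.60, 0.55 and 0.70. Of 40 lists the preset correlation called 16, another split of the 6 libraries 21, fry 20, and the estimated correlation 0 (4 at an unadjusted p under 0.05). That other split put both libraries of a line in 1 group, and other splits with 1 library of each line per group gave at most 13.

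**Figure D3:**
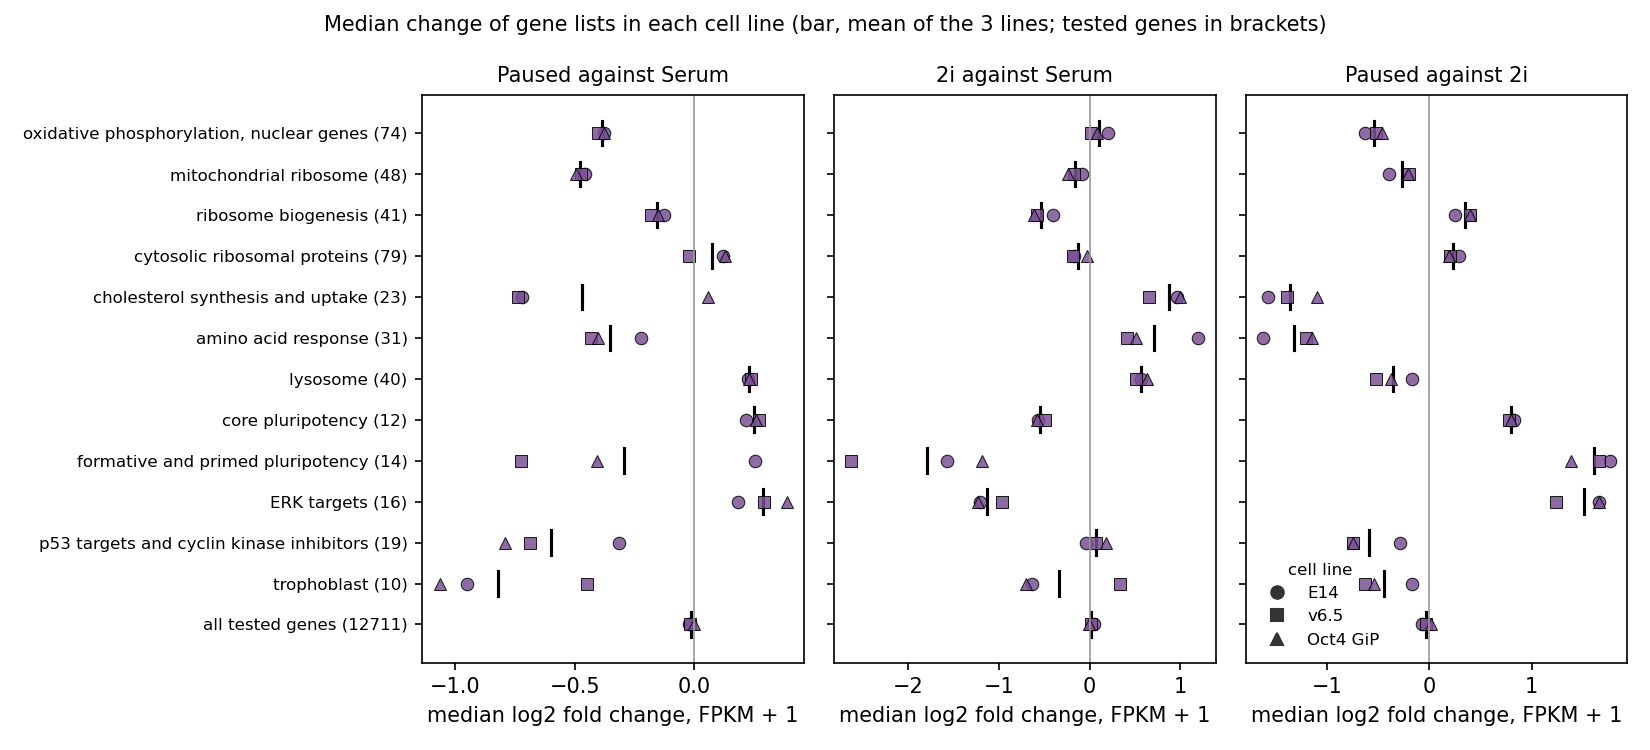
Median log2 fold change on the log2(FPKM + 1) scale (x axis) of the tested genes of 12 lists and of all genes (y axis) in each cell line, for the 3 comparisons, with a bar at the mean of the lines. In FPKM, oxidative phosphorylation lies at -0.39 and the lysosome at 0.23 for Paused against Serum. The authors' scale puts all 12 lists at a median under 0 there, and all genes at -0.88.

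Paused and 2i changes against Serum were set side by side, since both rest on the same 3 Serum libraries. Genes higher in both numbered 349, genes lower in both 502, and genes called in opposite ways 273. Independent lists of these sizes would share 211, 252.9 and 474.4 genes, an expectation that does not account for the shared Serum libraries. Groups simulated with no change against the same Serum libraries gave 0.02, 0.03 and 0. Almost no gene is called in such groups, so these values were near 0 by construction and do not measure an excess of overlap. Cpt1a and the mTor inhibitor Deptor rose in both, and Nes, a neural intermediate filament, and Ldha fell in both. Irak1, looked up in 2i after its values were seen, stood at 161 ± 38.6 FPKM there (log2 fold change 3.13 ± 0.14 against Serum). Ddit4 fell in Paused and rose in 2i, as did Nupr1, whose fall was not called without the line block. The fold changes correlated at 0.251 across genes and shared their sign in 58.7% of them. The simulated unchanged groups gave 0.50 and 66.7%, from the noise of the shared Serum libraries alone. The real values can therefore not be read against them as more or less sharing. Their covariance was 0.106 against 0.0379 (SD 0.0063) simulated, and 0.186 with a pseudocount of 0.1. The difference of 0.0678 exceeded the simulated SD and was smaller than the SD of the covariance over the lines, 0.0796. That SD is of covariances from single lines and is not the error of the value from all 3. It does therefore not show whether the difference lies within its error. The 3 Serum libraries cannot be split into groups of at least 2 each, so the shared controls could not be kept apart.

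**Figure D4:**
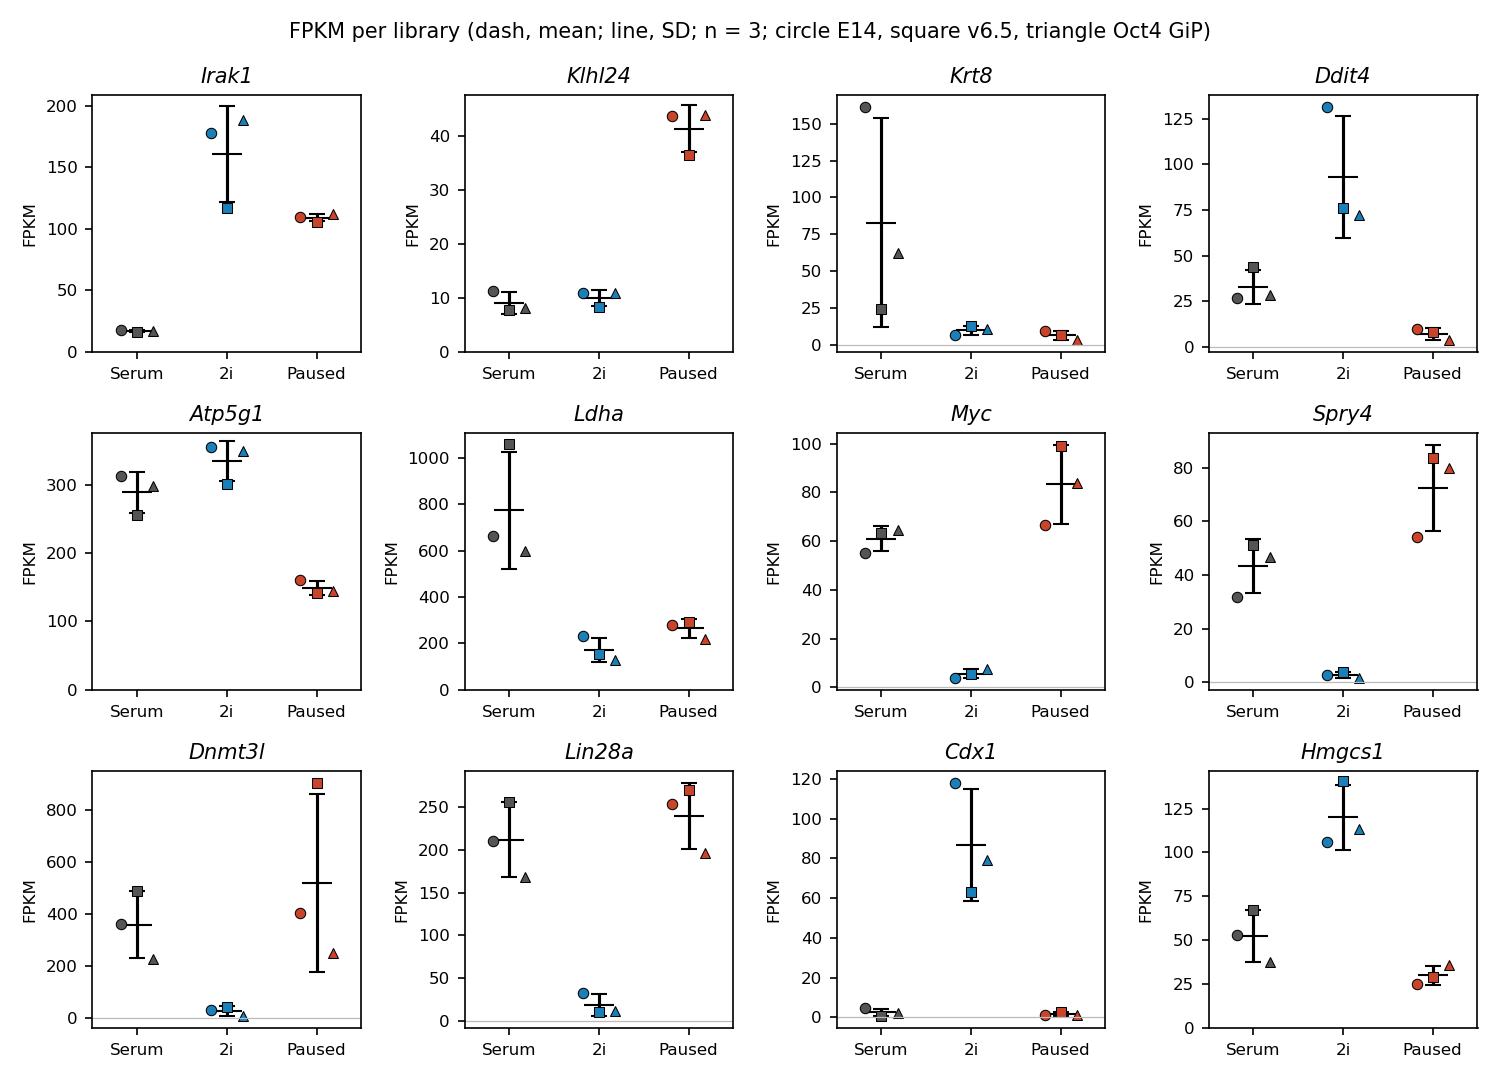
FPKM (y axis) of 12 named genes in the 3 conditions (x axis), with a symbol per library, a dash at the mean and a line for the SD (n = 3). Irak1 lies between 105.8 and 111.6 FPKM in Paused, between 116.5 and 188.3 in 2i and between 15.92 and 17.94 in Serum, and Ddit4 is lowest in Paused and highest in 2i.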

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

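The tests below were chosen after the result was seen, except the correction for transcript length and GC content and the counts of other splits, which were planned. The differences between lines were picked by a minimum of 0.3 in each direction, chosen after the medians were seen, and were not tested, with 1 library per line and condition. The interferon response median moved in opposite ways in the lines for 2i against Serum, at -0.67 in E14, 0.45 in v6.5 and 0.13 in Oct4 GiP, a span of 1.118. The primitive streak and mesoderm median spanned 2.025 in that comparison (-1.32, 0.71 and -0.68), and the trophoblast median 1.039 (-0.63, 0.34 and -0.70). For Paused against 2i the interferon response median spanned 0.761 (0.31, -0.45 and -0.20). Outside the named genes, 126 of 2938 tested entries without a gene name were higher and 94 lower in 2i than in Serum, and 142 and 133 for Paused against 2i. For Paused against Serum limma called 1 of these, against 514 at an unadjusted p under 0.05.

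Nuclear genes of oxidative phosphorylation and of the mitochondrial ribosome were lower in Paused than in Serum, with a joint median of -0.42 (SD 0.016 over the lines). After each library's trend on transcript length and GC content was removed, the median was -0.274 (SD 0.035). Length and GC content were those of the longest GENCODE transcript of each gene, which need not be the expressed one. The correction may therefore be incomplete, and the remaining median cannot exclude a bias of that kind as the whole cause. Such a bias may account for at least part. After the correction 32 of the 122 genes were called lower, against 74 before. Calls among all 11855 genes with a length went from 2180 to 1663. Loss of short transcripts would lower the cytosolic ribosomal proteins, which are shorter (median length 1059 against 1327.5 bases), and these stood at 0.075 (SD 0.083). This cannot decide against such a loss, since an effect of mTor inhibition on the ribosomal protein genes could offset it and was not tested. An effect of mTor inhibition on the 122 genes stays open as a hypothesis, found and tested on the same libraries.

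The authors' constant was lower in Paused than in Serum, at 0.524 of it. Loss of a few abundant transcripts while other genes kept their amount stays open: the median library difference in FPKM was 0.025 (SD 0.031), but summed FPKM ran from 1451983 to 2133969, and a scaling to the median gene, which may have been used, would set that difference near 0. Unequal spike-in or RNA input, a difference in RNA content and an origin unrelated to the amount of RNA cannot be told apart. In the table used here 0 rows are named as spike-in RNA, and how the constant was made is not given in the sources used here.

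Krt8, Krt18, Krt19, Tagln, S100a6, Sfn and Cnn1 were lower in Paused than in Serum. Fibroblast feeder cells in the Serum cultures would bring abundant collagen, and the highest ratio of a collagen gene to Tagln there was 0.0561 (Col1a1, SD 0.00705), which argues against feeder cells as their source. Differentiating ES cells in the Serum cultures may be a source: of 4 marker lists of other lineages, taken without Krt8 and Krt18, 3 had a median below 0 in all 3 lines. Of these, endoderm lay at -0.02 in v6.5, and the 4th list, ectoderm and neural markers, went both ways (0.08, -0.47 and 0.27). This stays open, because a few differentiating cells and a change within the ES cells cannot be told apart in bulk RNA.

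Other splits of the libraries were counted for every count of calls. For genes, 1 of the 10 splits of 6 libraries, the real one, gave as many calls in each comparison: 2311, 5161 and 5638, with 3 as the highest other in each, and relative to the median gene 2428, 5444 and 5825, also with 3. For lists, 1, 2 and 3 of the 10 splits gave as many: 21 against a highest other of 17, 20 against 20 and 16 against 21. Among the other splits with 1 library of each line per group, the highest were 11, 16 and 13. These 10 splits are too few for a share under 0.05. For the F test over the 3 conditions, 1 of 100 seeded splits, the real one, gave as many calls (6970, highest other 2240). These splits were drawn over all 9 libraries, and not within lines as the paired fit asks. Among those with 1 library of each line per group the highest other was 2090, and the number of such splits was not counted. The share among the 100 can therefore not exclude chance for that count. Only splits for which the model could be fitted were drawn, a limit set after a first result was seen.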

How the results depend on the processing

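The authors' columns and the omission of small RNA genes and joined symbols were chosen after the table was seen. The planned scaling to ERCC rows was not run, since 0 rows of the table used here are named as such. Of 476 calls of named genes 390 were kept under the 5 alternatives with all libraries that were run for them (centring, no line block, pseudocounts of 0.1 and 5, quantile normalisation), 247 also on leaving out each library, and 0 were reversed under these. In the authors' columns 25, 1 and 9 of the 138, 170 and 168 calls for Paused against Serum, 2i against Serum and Paused against 2i had the other sign. Where a cause is not named below, the cause was not tested. The calls for Paused against Serum (2311, and 2428 relative to the median gene) ran from 1 to 3268 and from 1 to 3319 when 1 library or line was left out. The value was 714, 36, 775, 36, 12, 1529 and 10 without Serum 1, Paused 1, Serum 2, Paused 2, Serum 3, 2i 3 and Paused 3, and relative to the median gene 988, 115, 938, 97, 10, 1604 and 15. Leaving out replicates 1, 2 and 3, that is E14, v6.5 and Oct4 GiP, gave 1, 5 and 2. The counts for 2i against Serum (5161 and 5444) ran from 1216 to 5242 and from 1290 to 5506, lowest without Oct4 GiP, and those for Paused against 2i (5638 and 5825) from 2041 to 5605 and from 2028 to 5736, also lowest without it. The count over the 3 conditions (6970) ran from 1272 to 6960, lowest without Oct4 GiP. With fewer libraries the variance has fewer degrees of freedom, and a lone library of a condition is assumed to vary like the others. With only the 6 libraries compared, 2i against Serum gave 2985 and 3262. Asking also for a log2 fold change of 1 or more left 279, 1610 and 1790 calls, 286, 1572 and 1776 relative to the median gene, and 2303 over the 3 conditions. Without a filter the relative count for Paused against Serum was 1284 with more genes tested. Without the line block, the paired fit's 2311, 5161 and 5638 became 1602, 4368 and 4797, and 60 of 516 results of named genes were no longer called. The authors' columns gave 9827 calls for Paused against Serum and 10894 over the 3 conditions, by their construction of 1 constant per library. They turned the overall level from 0.025 to -0.874 for Paused against Serum and from 0.109 to -0.243 for 2i against Serum, and moved it from -0.084 to -0.631 for Paused against 2i. For Paused against Serum the mean gave -0.025 and the 75th percentile -0.037. For 2i against Serum the level was 0.036 by the mean and by the 75th percentile, 0.082 with a pseudocount of 5, 0.063 without a filter and 0.09 with FPKM of 5 or more. The covariance of the Paused and 2i responses was 0.186 with a pseudocount of 0.1, against 0.106. List calls (21, 20 and 16) fell to 0 in each comparison when camera used an estimated correlation, and ran from 16 to 20, 17 to 23 and 14 to 17 without 1 line. The list of cytosolic ribosomal proteins turned from lower to higher in 2i against Serum under quantile normalisation (adjusted p = 0.2717, other alternatives 2e-05 to 0.635). Read depth is unknown, so its limit on low genes could not be given.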

Other observations

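The comparisons of cell lines were chosen after the data were examined, as were the neighbouring genes and the genes given per library. Between lines, limma called more genes for v6.5 than between the other lines. Levels in this paragraph are the mean ± SD of a line's 3 libraries, 1 per condition. The SD thus holds the differences between conditions and is not a spread of replicates. The p-values between lines also use the 3 conditions of a line in place of replicates, with condition means removed. A line has 1 library per condition, so its spread within a condition is unknown. Hprt is the purine salvage enzyme that is deleted in the E14Tg2a subline. It stood at 0.443 ± 0.144 FPKM in E14, 91.6 ± 33.1 in v6.5 and 77.0 ± 23.1 in Oct4 GiP. It was the 1 gene of 12711 that limma called between Oct4 GiP and E14, against 1646 at an unadjusted p under 0.05. Between v6.5 and E14 limma called 265 genes, 195 higher in v6.5, and between v6.5 and Oct4 GiP 70, 44 higher, against 2351 and 1961 at an unadjusted p under 0.05. The apolipoprotein Apoa2 stood at 35.3 ± 7.96 FPKM in v6.5 and 0.881 ± 0.589 in E14, and the neural factor Olig2 at 13.4 ± 4.31 and 0.0126 ± 0.0219. The bacterial sensor Nod1 stood at 10.6 ± 2.64 and 0.445 ± 0.19, and the vitamin D binding protein Gc at 9.42 ± 2.62 and 0.12 ± 0.123.

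Some neighbouring genes moved together, without a test for clustering. On chromosome 7 nephrin Nphs1 (30458315 to 30487223), its antisense gene Nphs1os inside it and the adhesion gene Kirrel2 (30447534 to 30457690) were higher in each Paused library than in each Serum library. Nphs1 stood at 101, 91.6 and 92.5 FPKM in Paused and 25.2, 17.3 and 17.9 in Serum, Nphs1os at 23.1, 24.8 and 25.3 against 7.47, 5.48 and 4.95, and Kirrel2 at 33.7, 36.4 and 35.0 against 10.9, 9.79 and 8.99. Without stated strand-aware counting, Nphs1 and Nphs1os are uncertain. On chromosome 13 Bhmt (93616675 to 93637961) and Dmgdh (93674433 to 93752833) stood at 17.2, 18.1 and 25.3 and at 11.1, 16.7 and 29.4 FPKM in 2i, and below 1.2 in the other 6 libraries. On chromosome 1 the Nodal inhibitors Lefty1 (180935022 to 180938400) and Lefty2 (180893108 to 180899103) stood at 0.492, 0.456 and 5.31 and at 0.509, 0.967 and 11.5 FPKM in 2i, and at 144, 80.7 and 197 and at 53.4, 29.8 and 92.6 in Paused.

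Some transcripts varied between lines or were listed at 0. Zscan4c, a marker of cells like the 2-cell embryo, stood at 28.9, 4.30 and 18.8 FPKM in Serum of E14, v6.5 and Oct4 GiP, at 0.399, 5.25 and 3.43 in 2i and at 7.55, 4.89 and 3.87 in Paused. The small RNA Scarna17, a guide for modifying spliceosomal RNA, was listed at 0, 0 and 240.5 FPKM in Serum, at 203, 469 and 654 in 2i and at 497, 478 and 244 in Paused. Scarna2 was listed at 0, 263 and 831 FPKM in Serum, at 0 in all 3 libraries of 2i and at 1146, 275 and 281 in Paused. The elongation factor Eef1a1 was listed at 0 in all 9 libraries.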
